A study of Homo sapiens with 8 samples.

How the data were processed

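Gene expression was measured on 8 Affymetrix arrays, 4 from each of 2 human T cell acute lymphoblastic leukaemia (T-ALL) lines, CCRF-CEM and HPB-ALL. Per the labels, cells were spinoculated with virus carrying a short hairpin RNA (shRNA), selected with puromycin and left for at least 2 weeks; total RNA was then labelled by the GeneChip WT Plus protocol. Each line has 1 array of cells with a scramble shRNA, 1 with the hairpin shTOX-1, 1 with the hairpin shTOX-2 and 1 of untransduced cells. The numbers 1 and 2 of the shTOX arrays name the hairpins, so the spread between shTOX arrays holds any difference between hairpins as well as between cultures. Nothing in the sources used here says that the arrays came from separate cultures: all p-values measure only the spread between these arrays, part of which may be technical.

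The deposited values are log2 intensities, 1 per probe set and array, as judged from their range and shape; the authors' background correction, summarization, normalization and software are not given in the sources used here. The 8 arrays had 53617 probe sets each, no missing values and medians between 4.62 and 4.71. With medians this close, a shift of all genes together cannot be read from these values. The number of arrays limits the precision.

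Of the probe sets, 16098 carried a single gene symbol and 37519 carried none in the annotation used here; the latter enter only the counts of unnamed probe sets. The Entrez identifiers of the 16098 all matched the reference annotation, with 0 differing symbols. They stood for 14884 genes; for the 779 genes with more than 1 probe set, the one with the highest mean was taken. Genes with a mean at or above the 40th percentile (log2 5.18) were tested, 8930 in all.

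Differences were estimated with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes without trend), and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. All fits used the 8 arrays. The comparison of 4 shTOX arrays with 4 control arrays (scramble and untransduced) and that of the lines came from a fit with line and shTOX as terms. A fit with 3 treatments and line gave shTOX against scramble, shTOX against untransduced, and scramble against untransduced. Another with a mean for each line and state gave the shTOX difference within each line and the difference of these differences. A fit with shTOX-1, shTOX-2 and controls gave the contrast of the hairpins. The TOX level also had an exact two-sided permutation test that moved the shTOX and control labels within each line. Values after ± are standard errors.

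Gene lists were written from general knowledge before the data were examined, as were the comparisons, the tests and the rule for named genes; 29 lists were fixed, of which 5 hold markers of other cell types. The others were the TOX family, non-homologous end joining, homologous recombination, other DNA repair, the V(D)J recombinase, p53 targets, apoptosis regulators, S phase, G2 and mitosis, cyclin-dependent kinase inhibitors and G1 cyclins, T cell receptor and signalling, thymocyte stage markers, T lineage transcription factors, NOTCH targets, MYC targets, T-ALL oncogenic transcription factors, exhaustion and inhibitory receptors, T cell activation and cytokines, interferon response, unfolded protein and integrated stress response, cholesterol biosynthesis, glycolysis and hypoxia, replication-dependent histones, and adhesion and migration. The marker lists covered B cells, myeloid cells, natural killer (NK) cells, erythroid cells and megakaryocytes, and fibroblasts and epithelial cells. Lists with at least 5 tested members, 20 in all, were tested with camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists; camera with an estimated correlation and fry were run beside it. Camera sets a list against all other genes, whereas fry asks whether its genes move, on balance, in the same direction. Within lists, p-values were also adjusted over the list alone.

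The rule for named genes took, for shTOX against controls, 10 higher and 10 lower genes with both shTOX arrays on the same side of both control arrays in each line; called genes came before others, which were taken by smallest p. It took 10 and 10 for the lines and 5 and 5 for each other comparison. From each list it took up to 6 called members by size, or else up to 4 by smallest p. Genes without a plain symbol were counted and not named: 106 of those called between shTOX and untransduced arrays, 13 of those called between scramble and untransduced arrays and 134 of those called between the lines.

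Similarity of the lines and of the hairpins was measured as a correlation across genes of their log2 differences; genes are not independent replicates, so no p was taken from it. For the lines, it was set against the 18 relabellings of 2 arrays as shTOX per line. For the hairpins, each was set against a different control so that no array was shared, and the value with shared controls was set against 100 simulations without any common effect.

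The fits were tested on simulated data with the spread of these arrays, in which 200 of 8930 genes were changed. For shTOX against controls, 47.8% of genes changed by 0.5 on the log2 scale were called, 98.5% of those changed by 1 and 100% of those changed by 2, along with 14 unchanged genes. That simulated spread was taken from the fit with 3 treatments and leaves out the difference between scramble and untransduced arrays, which the real comparison with both controls contains. For shTOX against scramble, 23.9% and 94.0% were called at 0.5 and 1; for the difference between lines, 1.49% and 34.3%. A list raised by 0.5 was called in 20 of 20 draws, with 1 call among unchanged lists. These lists were random genes that varied independently. False calls among real lists, whose genes can move together, were therefore not tested by this simulation. Splits of the real arrays, given at the end, bear on them.

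Alternatives were quantile normalization, median centring, no filter, a filter at the 60th percentile (log2 6.76), the mean over probe sets, eBayes with trend, eBayes with trend and robust, a replicate block (here the construct as a term shared by both lines), no line term, only the arrays of the treatments or of the line compared, an adjusted p under 0.1, a minimum log2 difference of 1, the other list tests, and leaving out each array in turn. Fits without the untransduced arrays were chosen after seeing the data. Raw scans were not used here.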

Results

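Expression was profiled in 2 established T-ALL cell lines, labelled CCRF-CEM and HPB-ALL, after lowering of TOX with an shRNA. TOX encodes a nuclear protein with an HMG-box DNA-binding domain that is needed for T cell development in the thymus. Each line gave 4 arrays: scramble shRNA, shTOX-1, shTOX-2 and untransduced cells. There was 1 array per line and construct, so replicates exist only across hairpins, control kinds and lines. Across the 8930 tested genes, arrays of the same line correlated at r = 0.949 to 0.985 and arrays of different lines at 0.876 to 0.908.

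TOX itself was lower in all 4 shTOX arrays than in the controls of the same line. In CCRF-CEM its log2 level was 11.03 in both the scramble and the untransduced array, 10.65 with shTOX-1 and 9.86 with shTOX-2. In HPB-ALL it was 10.59 with scramble, 10.64 untransduced, 10.16 with shTOX-1 and 8.75 with shTOX-2. Relative to the scramble array, 77.0% of TOX signal was left with shTOX-1 and 44.6% with shTOX-2 in CCRF-CEM, and 74.2% and 28% in HPB-ALL. Averaged over lines and hairpins, TOX stood at 51.3% of the controls, a log2 difference of -0.96 ± 0.28.

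This difference passed when adjusted over the list alone (TOX family, adjusted p = 0.0187) and missed the threshold over all genes (adjusted p = 0.292, rank 189 by p). The exact two-sided permutation test within lines gave p = 0.0556, the smallest value its 36 assignments allow. Adjusted over the list alone, the limma p was 0.0764 without the CCRF-CEM shTOX-2 array, 0.0549 without the HPB-ALL scramble array, 0.055 without the HPB-ALL untransduced array, 0.0827 without the line term and 0.0786 without both untransduced arrays, the last a fit chosen after seeing the data. The log2 difference was -0.77 ± 0.41 in CCRF-CEM and -1.16 ± 0.41 in HPB-ALL, with adjusted p = 0.582 and 0.612; their difference of 0.39 ± 0.58 had an adjusted p of 0.996. The relatives TOX2 and TOX4 differed by -0.03 each, and TOX3, at 4.73 to 5.10, was too dim to be tested.

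**Figure D1:**
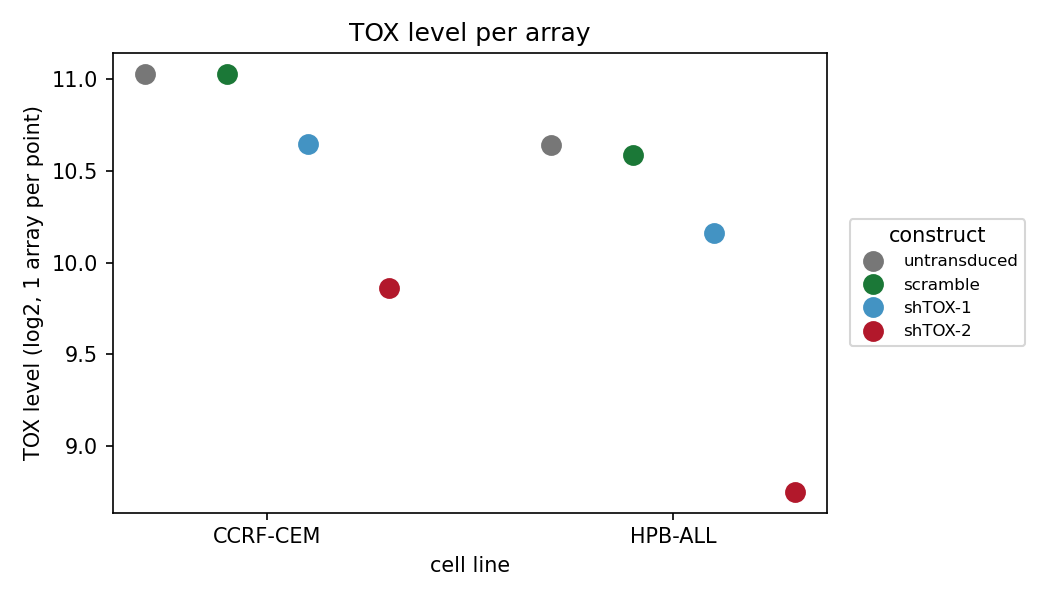
Log2 level of TOX (vertical axis) in each of the 8 arrays, grouped by cell line (horizontal axis) and coloured by construct; each point is 1 array. Both shTOX-2 arrays (9.86 and 8.75) lie below the shTOX-1 arrays (10.65 and 10.16), which lie below the controls of their line.

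The main comparison asked which genes go with lowered TOX when scramble and untransduced arrays together serve as controls. Among the 20 named genes, all with the shTOX arrays on the same side in both lines, the largest differences were in CCR8, a chemokine receptor, at -2.16 ± 0.46, CREB3L3, a membrane-bound transcription factor, at 1.24 ± 0.28 (2.36-fold higher), and MYLIP, a ubiquitin ligase that degrades the LDL receptor, at -1.03 ± 0.20 (2.04-fold lower). The shTOX mean of CCR8, 5.12, lay below the filter level of 5.18, so the size of its difference is limited by background, and against scramble alone it was -1.37 ± 0.37. HSD17B10, a mitochondrial dehydrogenase, was 1.90-fold higher (0.92 ± 0.15). The other higher genes were CYTOR (0.83), GPC3 (0.80), MREG (0.79), FJX1 (0.71), TFE3 (0.69), KIF1C (0.61), TTC1 (0.55) and LRP4 (0.47). The HPB-ALL means of GPC3 and the CCRF-CEM control mean of FJX1 lay below the filter level, which limits the size of their differences. The other lower genes were ZNF704 (-0.91 ± 0.16), LZTFL1 (-0.88 ± 0.16), FGF9 (-0.87), TARBP1 (-0.79), ZNF655 (-0.72), PCBP3 (-0.67), GPR21 (-0.64) and TNRC6B (-0.60). The shTOX means of ZNF704 (5.30), FGF9 (6.37) and PCBP3 (5.71) lay within a standard deviation of the filter level, as did the control mean of LRP4 (5.48). Background may therefore limit the size of these differences too.

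None of these genes, and none of the 8930 tested, passed in limma over all genes: 0 genes had an adjusted p under 0.05, and theirs lay between 0.283 and 0.292. An unadjusted p under 0.05 was found for 1277 genes, where 446 would be expected by chance, and 28 genes differed by at least 1 on the log2 scale. Both shTOX arrays lay on the same side of both controls, in the same direction in both lines, for 1014 genes (11.4%), 568 higher and 446 lower. Chance gives 5.56% for arrays that do not differ in kind, and 8.84% for independent lines with the observed shares of genes apart in 1 line, 43% in CCRF-CEM and 40.8% in HPB-ALL. Both values take the lines as independent. The untransduced arrays differed from the others alike in both lines (r = 0.574), which by itself raises the share on the same side. The 11.4% therefore cannot be read as an effect of lowered TOX. Against scramble alone, the differences of the lines had the same sign for 46.9% of genes. The shTOX arrays lay on opposite sides in the lines for 461 genes (5.16%). The count passing in limma was 4 without the CCRF-CEM scramble array, 1 without the HPB-ALL scramble array and 0 without both untransduced arrays. It was 16, CCR8, CYTOR, MREG and TARBP1 among them, in the replicate block, a fit with the construct as a term shared by both lines, which takes the differences between hairpins and between control kinds out of the error. The 16 also held SOSTDC1 (1.11) and KIF20A (0.76), which were called between scramble and untransduced arrays as well. In this fit a gene can therefore pass through the untransduced arrays alone, without a tie to lowered TOX.

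Genes of cell division stood higher in the shTOX arrays than in the mean of the controls. All 23 tested S phase genes and 24 of 25 genes of G2 and mitosis had positive differences, with medians of 0.305 and 0.338; examples are CCNE1, which drives entry into S phase, at 1.18 ± 0.36, CLSPN at 0.75 ± 0.25, the kinesin KIF11 at 0.60 ± 0.19 and BIRC5 at 0.74 ± 0.25. No single member passed, over all genes or adjusted over the list alone. As lists, both were called with camera (adjusted p = 1.53e-05 for S phase and 1.34e-06 for G2 and mitosis), and neither with an estimated correlation (adjusted p = 0.495 for each with an estimated correlation) or fry (0.262 each). In both lines the untransduced array stood apart here: relative to scramble, the median of the G2 and mitosis list was -0.793 in the CCRF-CEM and -0.655 in the HPB-ALL untransduced array, against -0.062 to 0.135 in the shTOX arrays, and that of S phase was -0.662 and -0.398, against -0.059 to 0.222.

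Cholesterol biosynthesis had positive differences in 15 of 16 genes, with a median of 0.553. Adjusted over the list alone, 6 were higher and 1 lower, against 0 over all genes; among them are the mevalonate kinase MVK at 0.97 ± 0.29, STARD4 at 0.86 ± 0.28, DHCR7 at 0.71 ± 0.23 and, lower, HSD17B7 at -0.44 ± 0.12. The list was called (camera adjusted p = 4.93e-05, and adjusted p = 0.495 with an estimated correlation). Its median relative to scramble was -0.462 in the untransduced CCRF-CEM array, with 0.564 and 0.345 in the shTOX-1 and shTOX-2 arrays, and -1.083 in the untransduced HPB-ALL array, with -0.118 and -0.140 in the shTOX arrays. MYC targets, here mostly genes of ribosome production such as RRS1 (0.55 ± 0.17) and NOP16 (0.54 ± 0.19), had 15 of 18 positive differences (camera adjusted p = 0.0129, and adjusted p = 0.567 with an estimated correlation). Relative to scramble their median was -0.567 in the untransduced CCRF-CEM array, with -0.064 and -0.242 in the shTOX arrays, and -0.078 in the untransduced HPB-ALL array, with 0.272 and 0.176 in the shTOX arrays.

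Interferon-response genes were positive in 15 of 22 members, with a median of 0.174. Adjusted over the list alone, IFIT3 (0.84 ± 0.25), HERC5 (0.68 ± 0.19), RSAD2 (0.58 ± 0.15) and IFIH1 (0.44 ± 0.11) were higher, each with an adjusted p of 0.0381, against 0 over all genes. The mean of IFIT3 in CCRF-CEM, 4.36, lay below the filter level of 5.18, so the size of its difference is limited by background there. The list was called with camera (adjusted p = 0.0225), with an adjusted p = 0.371 with an estimated correlation. Relative to scramble its median was -0.126 and -0.096 in the untransduced arrays of CCRF-CEM and HPB-ALL. In the shTOX arrays it was 0.038 and 0.067 in CCRF-CEM, and 0.138 and 0.265 in HPB-ALL.

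T cell identity genes lay in the other direction. All 15 tested genes of the T cell receptor and its signalling had negative differences, with a median of -0.298. Adjusted over the list alone, CD7 at -0.75 ± 0.17 (adjusted p = 0.0208) and CD5, which dampens T cell receptor signalling, at -0.70 ± 0.19 (adjusted p = 0.0272) were lower, against 0 over all genes; the kinase LCK was at -0.39 ± 0.13 and TRAT1 at -0.56 ± 0.21. The list was called with camera (adjusted p = 1.53e-05, and adjusted p = 0.371 with an estimated correlation; fry 0.151). Relative to scramble, its median was above 0 in both untransduced arrays (0.304 and 0.170) and below 0 in all 4 shTOX arrays (-0.135 to -0.678).

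Among thymocyte stage markers 15 of 20 were negative, with CD1E at -1.36 ± 0.45 and CD1B at -1.45 ± 0.62, both lipid-presenting molecules of cortical thymocytes, and KLF2 at -0.46 ± 0.16. CD1E and CD1B lay below the filter level of 5.18 in every HPB-ALL array, so their difference can be read in CCRF-CEM alone, where it was -2.46 ± 0.43 and -2.83 ± 0.68. T lineage transcription factors were negative in 16 of 19, with LEF1 at -0.58 ± 0.16, GATA3 at -0.37 ± 0.12, BCL11B at -0.26 ± 0.11 and IKZF2 at -0.60 ± 0.20. NOTCH targets were negative in 11 of 16, with 1 lower adjusted over the list alone, LZTFL1 (adjusted p = 0.00376), and MYC at -0.52 ± 0.15. Adhesion and migration had 9 of 14 negative, among them SELPLG at -0.53 ± 0.16. Relative to scramble, the NOTCH median was 0.188 and 0.225 in the untransduced arrays of CCRF-CEM and HPB-ALL, 0.094 and -0.108 in the shTOX arrays of CCRF-CEM and -0.037 and -0.098 in those of HPB-ALL. The untransduced medians were 1.101 and -0.260 for thymocyte stage, -0.008 and 0.093 for T lineage factors and 0.228 and -0.033 for adhesion, with all shTOX medians of these 3 lists below 0. Camera called all 4 lists as lower, with adjusted p = 0.00596 for thymocyte stage, 0.00149 for T lineage factors, 0.0129 for NOTCH targets and 0.0172 for adhesion. With an estimated correlation none held (adjusted p = 0.495 with an estimated correlation for thymocyte stage, and 0.371 for the other 3).

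The remaining lists were not called. For DNA repair, the camera adjusted p was 0.384 for non-homologous end joining (XRCC6 at 0.26, XRCC5 at 0.25), 0.485 for homologous recombination (RAD51B at -0.33, RAD51C at 0.36) and 0.129 for other repair genes (MSH6 at 0.44). It was 0.207 for p53 targets, 0.318 for apoptosis regulators, 0.611 for cyclin-dependent kinase inhibitors and G1 cyclins, 0.255 for the unfolded protein and integrated stress response and 0.25 for glycolysis and hypoxia. T-ALL oncogenic transcription factors (0.291) had a median of 0.017, a mean of -0.0173 and a test direction of lower; adjusted over the list alone, TAL1 was higher and LEF1, MYC and GATA3 were lower, all with an adjusted p of 0.0459. T cell activation and cytokines (0.868) had a positive median and mean (0.0293 and 0.0361) with a test direction of lower; adjusted over the list alone, XCL1 (-0.84 ± 0.18; adjusted p = 0.00854) was lower. The pro-apoptotic PMAIP1 (0.53 ± 0.14) was higher adjusted over the p53 list alone (adjusted p = 0.0374). Both recombinase genes, RAG1 and RAG2, were at -0.26, and the 4 tested exhaustion genes lay between -0.17 for LAG3 and 0.23 for EOMES. None of the replication-dependent histones was measured under its symbol here.

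In all, camera called 10 of the 20 lists, 5 of them as higher; 0 were called with an estimated correlation and 0 by fry. Camera called 6 lists without the HPB-ALL scramble array. Without both untransduced arrays, a fit chosen after seeing the data, it called 7.

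**Figure D2:**
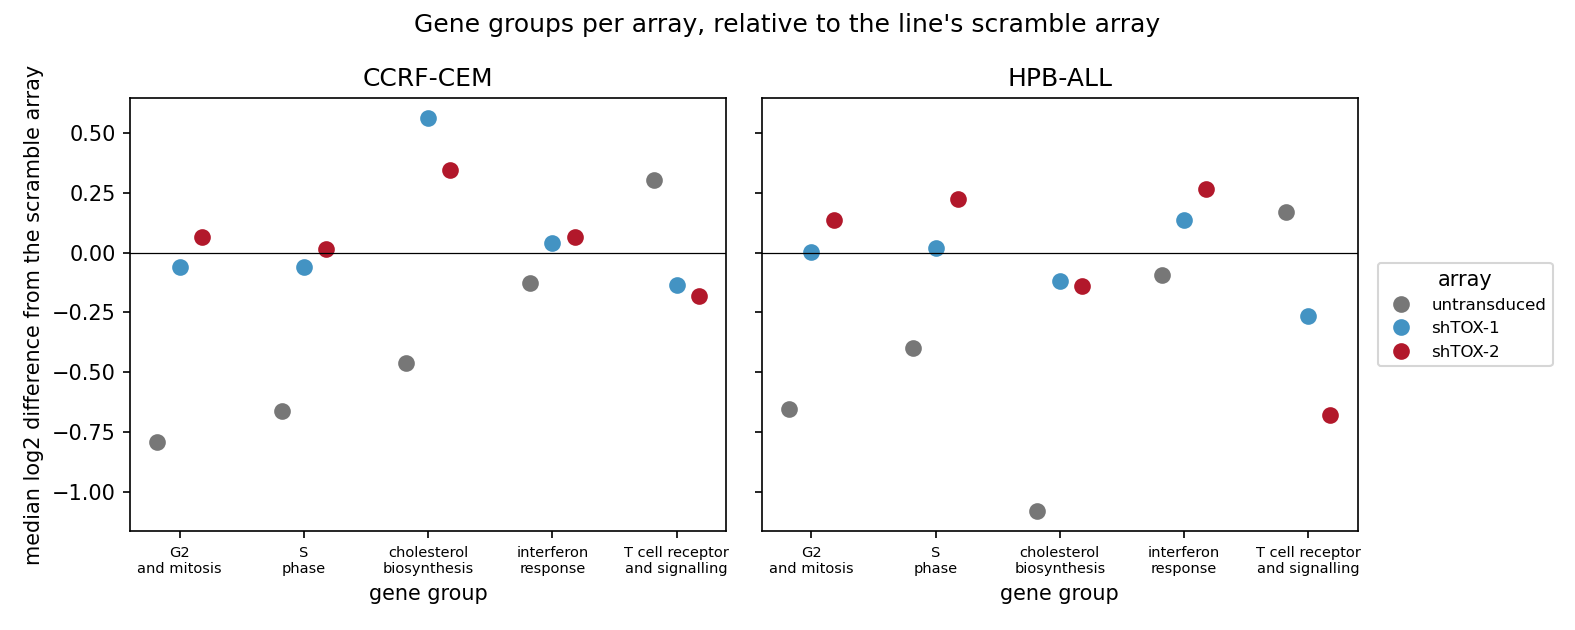
Median log2 difference from the scramble array of the same line (vertical axis) for 5 gene groups (horizontal axis), in the untransduced, shTOX-1 and shTOX-2 arrays of CCRF-CEM (left) and HPB-ALL (right); each point is the median over the tested genes of that group in 1 array. Genes of G2 and mitosis, S phase and cholesterol biosynthesis are lower in both untransduced arrays, and T cell receptor genes are below 0 in all 4 shTOX arrays.

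Set against scramble alone, the control that shares transduction and selection, the genes with the smallest p were DENND3 (-0.82 ± 0.14), FAT1 (-0.87 ± 0.17), ZNF704 (-0.86), LZTFL1 (-0.81) and ARHGAP33 (-0.55) on the lower side, and RAPGEF5 (0.91 ± 0.17), HSD17B10 (0.92 ± 0.18), GPC3 (0.89, with HPB-ALL levels below the filter level), FJX1 (0.78, from a scramble mean of 5.11, below the filter level) and MREG (0.58) on the higher side. RAPGEF5 had a scramble mean of 5.39 with a standard deviation of 1.99, so part of its levels lay below the filter level. TOX differed by -0.95 ± 0.35 (adjusted p = 0.93, and 0.0678 adjusted over the list alone). No gene passed in limma: 0 were called, 459 had an unadjusted p under 0.05 where chance gives 446, the smallest adjusted p was 0.835, and 1 was called without the HPB-ALL scramble array.

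Of the 5 lists called lower against both controls, 4 were also called lower against scramble. NOTCH targets were not, with 9 of 16 negative, a median of -0.0287 and a camera adjusted p of 0.48. T cell receptor genes were negative in 13 of 15 (median -0.303; camera adjusted p = 0.000432, and adjusted p = 0.402 with an estimated correlation), with CD5 at -0.70 ± 0.23 and CD7 at -0.62 ± 0.20. Adhesion and migration genes were negative in 13 of 14 (camera adjusted p = 0.00138, and adjusted p = 0.402 with an estimated correlation). Glycolysis and hypoxia, not called against both controls, were negative in 10 of 11, including HK2, the first enzyme of glycolysis, at -0.57 ± 0.17 and LDHA at -0.28 ± 0.12 (camera adjusted p = 0.00138, and adjusted p = 0.406 with an estimated correlation). The fall came largely from HPB-ALL, with medians relative to scramble of -0.384 and -0.512 in the shTOX arrays. The untransduced HPB-ALL array, at -0.643, also lay below scramble. In CCRF-CEM the medians were 0.020 with shTOX-1 and -0.197 with shTOX-2. Thymocyte stage markers, with CD1D at -1.02 ± 0.31, were called lower (camera adjusted p = 0.00942, and adjusted p = 0.631 with an estimated correlation), as were T lineage factors (camera adjusted p = 0.0352, and adjusted p = 0.406 with an estimated correlation). Interferon genes (camera adjusted p = 0.0404, and adjusted p = 0.406 with an estimated correlation) and cholesterol biosynthesis (camera adjusted p = 0.0352, and adjusted p = 0.786 with an estimated correlation) were called higher. For cholesterol biosynthesis the shTOX medians relative to scramble were positive only in CCRF-CEM (0.564 and 0.345), against -0.118 and -0.140 in HPB-ALL. Those of the interferon genes were small in CCRF-CEM (0.038 and 0.067) and larger in HPB-ALL (0.138 and 0.265). MYC targets (adjusted p = 0.839), S phase (median 0.0479; adjusted p = 0.511) and G2 and mitosis (median -0.00493; adjusted p = 0.597) were not called. Of single members, adjusted over the list alone, LZTFL1 was the 1 lower gene (adjusted p = 0.0305). Fry called 0 lists.

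Against untransduced cells, many genes changed. HMGCS1, an early enzyme of cholesterol synthesis, rose 4.16-fold (2.06 ± 0.24; adjusted p = 0.00369), CCNE1 3.43-fold (1.78 ± 0.30; adjusted p = 0.00991), the secreted antagonist SOSTDC1 3.35-fold, CREB3L3 2.91-fold and MVK 2.80-fold. HBEGF, a growth factor, fell (-3.29 ± 0.50; adjusted p = 0.00716), as did CCR8 (-2.94 ± 0.37; adjusted p = 0.00421), to a mean below the filter level. The fall of HBEGF was larger in CCRF-CEM, from 10.46 untransduced to 5.87 and 5.75 with the hairpins. In HPB-ALL it went from 6.79 to 4.86 and 4.85, below the filter level, so its size there is limited by background. ERN1, a sensor of unfolded proteins, was 4.84-fold lower (-2.28 ± 0.21), the stress-induced pseudokinase TRIB3 4.05-fold lower (-2.02 ± 0.19) and KLHDC7B 4.03-fold lower (-2.01 ± 0.17). TOX differed by -0.98 ± 0.35, with an adjusted p of 0.103, and 0.0608 adjusted over the list alone. Without the HPB-ALL shTOX-1 array its adjusted p over all genes was 0.0455 (-1.22 ± 0.31).

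In the 4 shTOX against the 2 untransduced arrays, 1056 genes were called, 552 higher and 504 lower; 150 of them differed by at least 1 on the log2 scale, 65 higher and 85 lower. The count depended on the untransduced arrays: it was 29 without that of CCRF-CEM and 349 without that of HPB-ALL. It was 570 without the HPB-ALL shTOX-2, 608 without the CCRF-CEM shTOX-1 and 654 without the CCRF-CEM shTOX-2 array, and 1 in a fit without the line term.

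Cell division genes rose together. Of 25 genes of G2 and mitosis 21 rose and 4 did not pass (24 higher adjusted over the list alone), among them the mitotic kinesin KIF20A (1.37 ± 0.12), the cyclins CCNB1 (1.34 ± 0.17) and CCNA2 (1.03 ± 0.16), BIRC5 (1.23 ± 0.14), HMMR (1.05 ± 0.15) and BUB1 (1.01 ± 0.12). Of 23 S phase genes 15 rose (17 adjusted over the list alone), with CLSPN at 1.18 ± 0.20, FEN1 at 1.10 ± 0.14, and the helicase subunits MCM2 (0.81 ± 0.14) and MCM5 (0.74 ± 0.15). Other repair genes rose in 5 of 11 (6 adjusted over the list alone): UNG (1.01), MSH6 (0.73), PARP1 (0.71), CHEK2 (0.55) and XRCC1 (0.47). Camera adjusted p-values were 2.71e-16, 1.45e-10 and 0.00913. With an estimated correlation, none of the 3 was called (adjusted p = 0.222, 0.29 and 0.307 with an estimated correlation).

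Cholesterol biosynthesis rose in 11 of 16 genes (13 higher and 1 lower adjusted over the list alone), with SQLE at 1.46 ± 0.20, MSMO1 at 1.37 ± 0.20, STARD4 at 1.28 ± 0.27 and MVD at 1.16 ± 0.22 beside HMGCS1 and MVK (camera adjusted p = 3.23e-08, and adjusted p = 0.333 with an estimated correlation). MYC targets rose in 4 of 18 (6 adjusted over the list alone), NOP16 (0.82), RRP12 (0.70), NCL (0.66) and the polyamine enzyme ODC1 (0.66; camera adjusted p = 0.00114, and adjusted p = 0.545 with an estimated correlation). Of the interferon genes 5 rose, among them IFIT3 (1.20 ± 0.23), IFIT1 (1.13 ± 0.28), HERC5 (0.91) and RSAD2 (0.69), and 2 fell, TRIM22 (-0.78) and IRF9 (-0.61), out of 22 (7 and 2 adjusted over the list alone); this list was not called (camera adjusted p = 0.0845). In CCRF-CEM the means of IFIT3 and IFIT1 lay below the filter level, so the size of their differences is limited by background there.

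Fewer members fell. In the T cell receptor list CD7 (-0.89 ± 0.20) and TRAT1 (-0.82 ± 0.21) fell out of 15 (also 2 adjusted over the list alone; camera adjusted p = 0.000912, and adjusted p = 0.29 with an estimated correlation). Of 19 T lineage factors EGR1 (-0.90) and LEF1 (-0.76) fell (4 adjusted over the list alone; camera adjusted p = 0.00398, and adjusted p = 0.29 with an estimated correlation), and of 16 NOTCH targets LZTFL1 (-0.95; 5 adjusted over the list alone; camera adjusted p = 0.00485, and adjusted p = 0.281 with an estimated correlation). The stress genes TRIB3 and DDIT3 (-1.75 ± 0.15) were the 2 of 14 unfolded protein and integrated stress response genes that fell (also 2 adjusted over the list alone; camera adjusted p = 0.0422, and adjusted p = 0.545 with an estimated correlation). Relative to scramble the median of this list was 0.657 untransduced and 0.098 with each hairpin in CCRF-CEM. In HPB-ALL it was -0.101 untransduced, -0.089 with shTOX-1 and -0.055 with shTOX-2, so by its median the list fell in CCRF-CEM alone. Thymocyte stage markers were called lower (camera adjusted p = 0.0392, and adjusted p = 0.545 with an estimated correlation) with 15 of 20 negative, yet the 1 member that passed, the lymph-node homing receptor CCR7, rose by 1.12 ± 0.25 (1 higher and 2 lower adjusted over the list alone). In total camera called 10 lists, 0 held with an estimated correlation, and fry called 9.

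In the lists not called, single members passed. XRCC5 rose (0.45) out of 7 end-joining genes, RAD54B (0.48) out of 13 recombination genes and PMAIP1 (0.63) out of 12 p53 targets. Out of 18 apoptosis regulators, the anti-apoptotic BIRC5 and the pro-apoptotic PMAIP1 rose, and the pro-apoptotic BCL2L11 (-0.48) fell. Adjusted over the list alone these lists gave 2, 4 and 3 higher, with 2 lower in recombination, and again 2 higher and 1 lower for apoptosis. HHEX (1.30 ± 0.22), ERG (0.76) and TAL1 (0.65) rose and LEF1 fell among 15 oncogenic factors (3 higher and 6 lower adjusted over the list alone), a list with positive median and mean (0.0334 and 0.0399) and a test direction of lower. CCL5 (0.54) rose and XCL1 (-0.98), EGR1 and FOS (-0.80) fell among 8 activation genes (also 1 and 3 adjusted over the list alone), with a median of 0.172, a mean of -0.0483 and a test direction of lower. ICAM2 (-0.90), SELPLG (-0.71) and ICAM1 (-0.65) fell and CCR7 rose among 14 adhesion genes (2 higher and 3 lower adjusted over the list alone), and VEGFA (-1.56 ± 0.42) fell among 11 glycolysis and hypoxia genes (0 adjusted over the list alone; median 0.135, mean -0.0454, test direction higher). VEGFA fell mainly in CCRF-CEM, from 7.65 untransduced to 4.91 and 5.02 with the hairpins, below the filter level. In HPB-ALL it was 8.81 untransduced, 8.57 with shTOX-1 and 8.20 with shTOX-2.

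Scramble and untransduced arrays were compared to see what differs without a TOX hairpin; any other difference between these cultures enters this comparison as well. DDIT3, the stress-induced factor CHOP, was 4.28-fold lower with scramble (-2.10 ± 0.17; adjusted p = 0.00312), ERN1 6.63-fold lower (-2.73 ± 0.24; adjusted p = 0.00369), TRIB3 4.25-fold lower (-2.09 ± 0.22; adjusted p = 0.0104), and ATF5 4.59-fold lower (-2.20 ± 0.30; adjusted p = 0.0293). HBEGF fell as well (-3.43 ± 0.58; adjusted p = 0.0343), from 10.46 to 5.54 in CCRF-CEM and from 6.79 to 4.86 in HPB-ALL. The last value lay below the filter level, so the size of the fall in HPB-ALL is limited by background. CCR7 rose 3.41-fold (1.77 ± 0.28), HMGCS1 3.12-fold (1.64 ± 0.28), SOSTDC1 2.42-fold and KIF20A 2.32-fold (1.22 ± 0.14; adjusted p = 0.0145), and HMGB3 rose by 1.40 ± 0.20 from a mean of 5.03, below the filter level. TOX did not differ detectably (-0.02 ± 0.40; adjusted p = 0.983).

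With 2 arrays on each side, 95 genes were called, 52 higher and 43 lower, and 48 of them differed by at least 1 on the log2 scale. Each of the 52 was also called higher in shTOX than in untransduced arrays, where independent lists would share 3.21, and 42 of the 43 were called lower (2.43 for independent lists); both comparisons use the same untransduced arrays, which alone makes them alike. The count depended on most arrays: it was 3 without the CCRF-CEM shTOX-2, 4 without the CCRF-CEM untransduced, 7 without the CCRF-CEM scramble, 17 without the HPB-ALL scramble, 27 without the HPB-ALL shTOX-2, 40 without the HPB-ALL shTOX-1 and 59 without the HPB-ALL untransduced array. It was 162 with a stricter filter, 182 with trend, 220 with trend and robust, and 0 without the line term.

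Of 25 genes of G2 and mitosis 8 rose (23 adjusted over the list alone), including CCNB1 (1.14 ± 0.20) and HMMR (1.10 ± 0.17), and all 25 were positive (camera adjusted p = 1.62e-20, and adjusted p = 0.147 with an estimated correlation). FEN1 (1.01), UNG (1.00) and RRM2 (0.80) rose out of 23 S phase genes (16 adjusted over the list alone; camera adjusted p = 3.37e-12, and adjusted p = 0.317 with an estimated correlation). In cholesterol biosynthesis HMGCS1 and EBP (0.78 ± 0.15) rose out of 16 (12 adjusted over the list alone; camera adjusted p = 6.6e-09, and adjusted p = 0.421 with an estimated correlation). UNG was the 1 of 11 other repair genes that rose (5 adjusted over the list alone; camera adjusted p = 0.00311, and adjusted p = 0.317 with an estimated correlation). MYC targets were called higher with 0 of 18 members passing (0 adjusted over the list alone; camera adjusted p = 0.000589, and adjusted p = 0.6 with an estimated correlation). Called lower were NOTCH targets, with 0 of 16 members passing and PTCRA at -1.85 ± 0.51 (0 adjusted over the list alone; camera adjusted p = 0.0193, and adjusted p = 0.317 with an estimated correlation), and the stress response, with DDIT3 and TRIB3 of 14 passing (also 2 adjusted over the list alone; camera adjusted p = 0.0265, and adjusted p = 0.6 with an estimated correlation). For the stress response the untransduced median relative to scramble was 0.657 in CCRF-CEM and -0.101 in HPB-ALL. By its median, that list was lower with scramble in CCRF-CEM alone. Fry called 2 lists.

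Within CCRF-CEM, the genes with the smallest p included the lipid-presenting CD1E and CD1D. CD1E was at -2.46 ± 0.43 (5.51-fold lower) and CD1D at -1.40 ± 0.27; from the thymocyte list, CD1B was at -2.83 ± 0.68 and CD1A at -2.28 ± 0.47. ZNF704 (-1.29 ± 0.16), the prostaglandin-degrading enzyme HPGD (-1.15 ± 0.14) and the cadherin FAT1 (-0.97 ± 0.19) were also lower, and the interferon-induced GBP5 (1.52 ± 0.26), GPC3 (1.16 ± 0.17), TCF4 (0.93), PCDH9 (0.75) and OSBPL1A (0.68) higher. Over all genes limma called 0, with 821 at an unadjusted p under 0.05 and a smallest adjusted p of 0.125, that of ZNF704 and HPGD. Without the CCRF-CEM scramble array 63 genes were called, and without both untransduced arrays 1 gene was.

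Thymocyte stage markers were negative in 15 of 20 in CCRF-CEM, and 6 were lower adjusted over the list alone, with an adjusted p of 0.00661 for CD1A, CD1D and CD1E. The list was called lower with camera (adjusted p = 0.000586, and adjusted p = 0.811 with an estimated correlation). In the scramble array, CD1A (8.97), CD1B (7.45), CD1C (8.74) and CD1E (9.25) were themselves below the untransduced array (10.37, 9.94, 10.17 and 10.41), and the shTOX arrays lay lower still, down to 6.91, 5.39, 7.39 and 6.81 with shTOX-2. CD1D was 7.84 untransduced, 8.49 with scramble, 7.04 with shTOX-1 and 6.48 with shTOX-2. Cholesterol biosynthesis was called higher (camera adjusted p = 7.53e-05, and adjusted p = 0.811 with an estimated correlation; 4 higher and 1 lower adjusted over the list alone), as were G2 and mitosis (0.000265) and S phase (0.00483; both adjusted p = 0.896 with an estimated correlation). T cell receptor genes were called lower (camera adjusted p = 0.0407, and adjusted p = 0.811 with an estimated correlation).

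**Figure D3:**
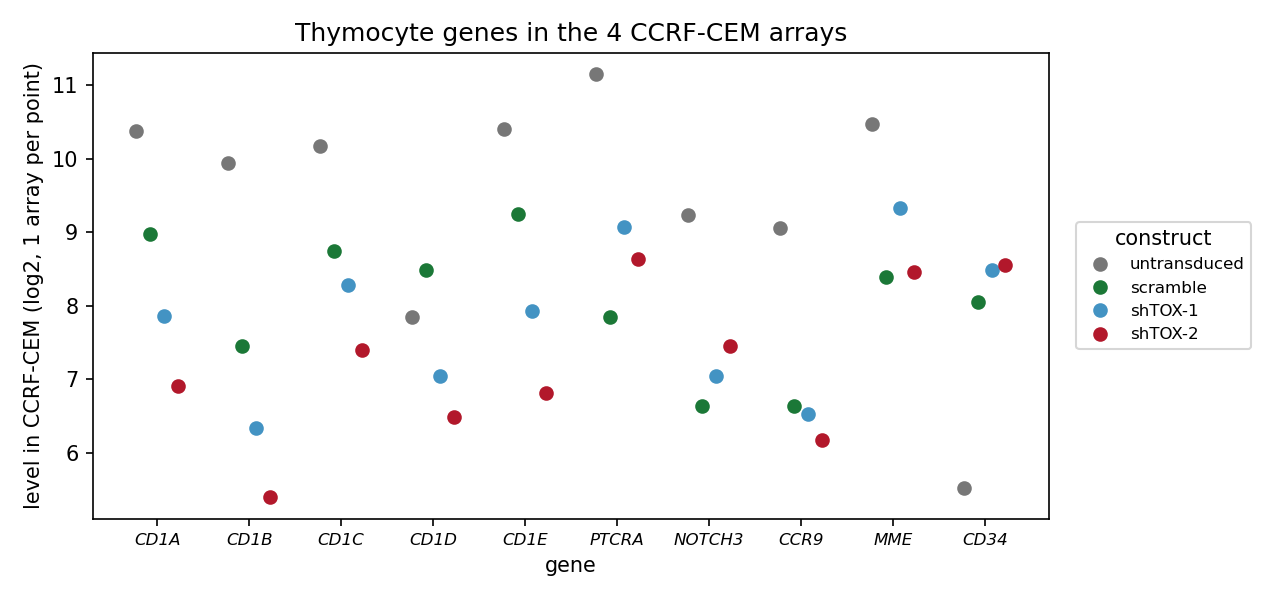
Log2 level (vertical axis) of 10 genes of thymocyte development (horizontal axis) in the 4 CCRF-CEM arrays, coloured by construct; each point is 1 array, and the genes were chosen after their values were seen. CD1A runs from 10.37 in the untransduced to 6.91 in the shTOX-2 array, whereas CD34 is 5.52 untransduced and 8.05 to 8.55 in the transduced arrays.

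Within HPB-ALL the genes with the smallest p on the lower side were the proteoglycan SRGN at -2.15 ± 0.31 (4.43-fold), CHI3L2 at -1.85 ± 0.27, complement factor D (CFD) at -1.33 ± 0.18, the adaptor TYROBP at -1.32 ± 0.21 and CD5 at -1.16 ± 0.17. HSD17B10 (1.09 ± 0.20), RSAD2 (0.86), CEP162 (0.82), RASGRP3 (0.79) and FJX1 (0.79) were higher. Limma called 0 genes, with 677 at an unadjusted p under 0.05, a smallest adjusted p of 0.212, and 1 called without the HPB-ALL shTOX-1 array. T cell receptor genes were negative in 13 of 15 and called lower as a list (camera adjusted p = 8.66e-07, and adjusted p = 0.23 with an estimated correlation); CD5, CD7 (-0.997 ± 0.229) and LCK (-0.64 ± 0.15) were lower adjusted over the list alone, with adjusted p = 0.00143, 0.012 and 0.012.

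Camera called 9 more lists in HPB-ALL. T lineage factors were called lower, with 17 of 19 negative (camera adjusted p = 0.000238, and adjusted p = 0.23 with an estimated correlation), as were NOTCH targets (0.0116, and adjusted p = 0.361 with an estimated correlation), oncogenic factors (0.0165, and adjusted p = 0.23 with an estimated correlation) and adhesion (0.0116, and adjusted p = 0.351 with an estimated correlation), where CCR4 at -1.19 ± 0.24 was lower adjusted over the list alone (adjusted p = 0.014). Interferon genes were called higher (camera adjusted p = 0.005, and adjusted p = 0.23 with an estimated correlation), with RSAD2 and IFIT3 (1.23 ± 0.32) higher adjusted over the list alone (adjusted p = 0.0298 and 0.0472). S phase and G2 and mitosis (camera adjusted p = 0.000147 each), MYC targets (0.000478) and cholesterol biosynthesis (0.0283) were also called higher, with adjusted p = 0.554 for the first 3 and 0.634 for the last with an estimated correlation.

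Whether the lines differed in their response was tested directly. No gene passed: limma called 0 for the difference of differences, 410 had an unadjusted p under 0.05, fewer than the 446 expected by chance, and the smallest adjusted p was 0.811; 4 were called without the CCRF-CEM scramble array. The genes with the smallest p were HPGD (-1.39 ± 0.20), CD1A (-2.93 ± 0.66), DPY19L2P2 (-1.25), RPL14 (-0.96) and CEP162 (-0.87), lower in CCRF-CEM relative to HPB-ALL, and CHI3L2 (2.09 ± 0.38), CFD (1.54 ± 0.25), BCAM (1.41), TYROBP (1.36) and GP5 (1.20). CD1A was lower adjusted over the thymocyte list alone (adjusted p = 0.0371), but its level of 3.66 to 4.82 in the HPB-ALL arrays lay below the filter level of 5.18, so a fall could not be measured there. A camera adjusted p of 0.046 was found for 3 lists, of which none held (adjusted p = 0.834, 0.829 and 0.836 with an estimated correlation): T cell receptor genes, with medians of -0.242 in CCRF-CEM and -0.413 in HPB-ALL, T-ALL oncogenic factors, with 0.145 and -0.131, and thymocyte stage markers, with -0.384 and -0.15. Of the 20 thymocyte markers 7, among them CD1A, CD1B, CD1C and CD1E, lay below that level in every HPB-ALL array, and without these 7 the median difference between the lines was -0.176 in place of -0.327.

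Across genes, the shTOX minus control differences of the lines, which share no array, correlated at r = 0.378 (rho 0.357), and 63.1% of genes had the same sign. This was the second highest of 18 relabellings of the arrays; the highest, 0.435, took scramble and untransduced of CCRF-CEM with shTOX-1 and untransduced of HPB-ALL. The similarity depended on the untransduced arrays: r was -0.0515 against scramble alone and 0.571 against untransduced alone, and scramble minus untransduced gave 0.371. Leaving out the untransduced CCRF-CEM array gave 0.121, and the untransduced HPB-ALL array 0.0543.

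**Figure D4:**
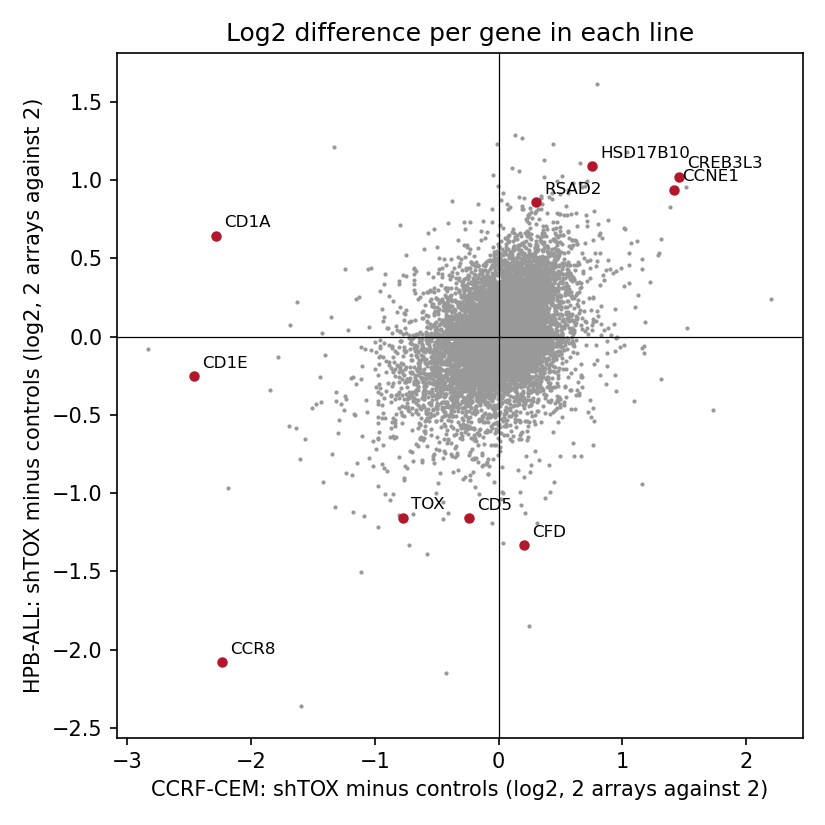
Log2 difference of shTOX minus control arrays in CCRF-CEM (horizontal axis) and HPB-ALL (vertical axis) for each tested gene (grey), with 10 genes named (red), chosen for display after their values were seen. The differences correlate at r = 0.378 across genes, CCR8 and TOX are below 0 on both axes, and CD1A and CD1E are below 0 in CCRF-CEM.

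The hairpins lowered TOX to different degrees. TOX was 1.10 ± 0.20 higher with shTOX-1 than with shTOX-2 (2.14-fold; adjusted p = 0.401; 0.00137 adjusted over the list alone), rank 5 of all genes by p. POGLUT2 (1.31 ± 0.18), SERHL2 (1.18, with an shTOX-2 mean of 4.85, below the filter level), REEP3 (0.89) and DCK (0.87) were also higher with shTOX-1, and KRCC1 (-0.88), SHANK1 (-0.83), PIM1 (-0.72), ZNF41 (-0.61) and SIAE (-0.57) higher with shTOX-2. No gene passed in limma (0 called; 381 at an unadjusted p under 0.05; smallest adjusted p 0.346). Adjusted over the list alone, XRCC4 (0.76 ± 0.16; adjusted p = 0.0084) and the NOTCH target DTX1 (1.07 ± 0.24; adjusted p = 0.0311) were higher with shTOX-1. Camera called S phase, with 20 of 23 negative (adjusted p = 0.0274, and adjusted p = 0.987 with an estimated correlation), and T cell activation and cytokines, with 7 of 8 negative (adjusted p = 0.0274, and adjusted p = 0.694 with an estimated correlation), both higher with shTOX-2.

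Set against different controls, so that no array was shared, the differences of shTOX-1 and shTOX-2 correlated across genes at r = 0.251 and 0.252. With both controls shared the value was 0.672, where simulation without a common effect gives 0.333, and with scramble shared it was 0.514, where simulation gives 0.5. In the simulation the untransduced arrays differ from the others only by noise. The real untransduced arrays stood apart from all transduced arrays, which by itself raises the value with both controls shared. The gap between 0.672 and 0.333 therefore cannot be read as an effect common to the hairpins. The value without a shared array was 0.131 without the CCRF-CEM scramble array and 0.144 without the CCRF-CEM shTOX-1 array.

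The lines themselves differed in the most genes. CCRF-CEM had higher C8orf88 (5.83 ± 0.14), ZNF141 (5.60), ZNF43 (5.43), MNS1 (4.95), ZNF184 (4.91), NETO1, DSG2, CD1E (4.61 ± 0.45), POGLUT3 and RORB. HPB-ALL had higher CEP192P1 (-5.29), PLEK (-5.05), CYTL1 (-4.77 ± 0.39), RGN (-4.55), the interferon-induced IFIT3 (-4.00) and IFIT2 (-3.44), TNIK, BAMBI, STX3 and SPRY2. For 18 of these genes the mean of the dimmer line lay below the filter level of 5.18, so no fold is given. With 4 arrays on each side, 2443 genes were called, 1111 higher in CCRF-CEM and 1332 higher in HPB-ALL, and 735 of them differed by at least 1 on the log2 scale (401 and 334). For these 20 named genes the adjusted p was 3.97e-05 for CD1E and smaller for the others.

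All 15 T cell receptor genes were higher in CCRF-CEM (also 15 adjusted over the list alone), with UBASH3A at 3.56 ± 0.16, SH2D1A at 3.22 ± 0.31, CD28 at 2.88 ± 0.26 and LCK at 2.40 ± 0.13 (camera adjusted p = 4.88e-13, and adjusted p = 0.0941 with an estimated correlation). Thymocyte stage markers were higher in 16 and lower in 1 of 20 (18 and 1 adjusted over the list alone), among them CD1A (4.37), CD1C (4.29), CD44 (4.02), CD1B (3.58) and CD38 (3.39; camera adjusted p = 5.79e-10, and adjusted p = 0.177 with an estimated correlation). In HPB-ALL the means of CD28, CD1A, CD1C, CD44 and CD1B lay below the filter level, so the size of these differences is limited by background, as for 335 of the 2443 genes called between the lines. Adhesion genes were higher in 7 and lower in 3 of 14 (8 and 3 adjusted over the list alone), with S1PR1 at 3.23, CD99 at 2.94 and ICAM1 at -2.20 (camera adjusted p = 0.0372, and adjusted p = 0.369 with an estimated correlation). In HPB-ALL 9 of 14 stress-response genes were higher (also 9 adjusted over the list alone), ASNS (-2.52), VLDLR (-2.02) and SESN2 (-1.61) among them (camera adjusted p = 0.000124, and adjusted p = 0.369 with an estimated correlation). Fry called 7 lists.

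Other lists held called members in both directions, without a camera call. Interferon genes were higher in CCRF-CEM for 5 and in HPB-ALL for 6 of 22 (6 and 7 adjusted over the list alone), with XAF1 at 3.27 and IFIT1 at -2.56. Of 18 apoptosis regulators 5 were higher and 6 lower (also 5 and 6 adjusted over the list alone), BCL2 at -1.47 ± 0.20 and BCL2L1 at 1.21 ± 0.14, both survival factors, in opposite directions. Of 12 p53 targets 1 was higher and 6 lower (also 1 and 6 adjusted over the list alone), with PMAIP1 at -1.64. NOTCH targets were higher for 5 and lower for 3 of 16 (6 and 3 adjusted over the list alone), with PTCRA at 2.35, NOTCH3 at 2.14 and NRARP at -2.16. In CCRF-CEM the means of IFIT1, NRARP and CCND2 lay below the filter level. The D cyclins CCND2 (-2.16 ± 0.12) and CCND3 (0.90 ± 0.17) differed in opposite directions. Oncogenic factors were higher in CCRF-CEM for 5 of 15 (also 5 adjusted over the list alone), among them BCL11B (1.27) and TAL1 (0.73). Glycolysis and hypoxia genes were higher in HPB-ALL for 4 of 11 (also 4 adjusted over the list alone), with VEGFA at -2.90 and BNIP3 at -2.33.

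Markers of other cell types were mostly dim. The brightest of each list by mean level were VPREB1 (6.26) for B cells, CD68 (6.98) for myeloid cells, NCR3 (6.17) for NK cells, EPOR (7.14) for erythroid cells and megakaryocytes, and KRT18 (7.43) for fibroblasts and epithelial cells. In single HPB-ALL arrays the myeloid MPO varied more, at 7.03 with scramble, 5.10 with shTOX-1, 7.94 with shTOX-2 and 4.83 untransduced. Of the 14 tested markers none passed between shTOX and controls. VPREB1, a surrogate light chain of early lymphocytes, was 0.67 ± 0.20 higher in shTOX arrays, with an adjusted p of 0.3 over all genes and 0.0163 adjusted over the list alone; it rose against untransduced arrays (0.93 ± 0.21; adjusted p = 0.0235).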

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

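For 3 gene lists a camera test of the difference in shTOX effect between the lines, which was planned ahead, passed, but none held with an estimated correlation, and fry called 0. The difference, CCRF-CEM minus HPB-ALL, had a median of 0.364 for T cell receptor and signalling genes (camera adjusted p = 0.046, and adjusted p = 0.834 with an estimated correlation), which were below the controls in both lines. It was 0.256 for T-ALL oncogenic transcription factors (adjusted p = 0.046, and adjusted p = 0.829 with an estimated correlation), with medians of 0.145 in CCRF-CEM and -0.131 in HPB-ALL, and -0.327 for thymocyte stage markers (adjusted p = 0.046, and adjusted p = 0.836 with an estimated correlation), with -0.384 and -0.15. Of the 20 thymocyte markers 7, CD1A, CD1B, CD1C, CD1E, RAG1, CD34 and CD44, lay below the filter level of 5.18 in every HPB-ALL array, so a fall could not be measured there, and without them the median difference was -0.176. No single gene passed over all genes.

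Probe sets without a gene name in the annotation used here carried differences in data that the comparisons above leave out. Of 13009 tested, 553 were called between shTOX and untransduced arrays, 160 of them higher, 17 between scramble and untransduced arrays, 4 of them higher, and 2017 between the lines, 917 of them higher in CCRF-CEM. Between shTOX and controls 0 were called, with 1751 at an unadjusted p under 0.05.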

How the results depend on the processing

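Of 219 recomputed counts, levels and correlations, 178 stayed the same. For a count this meant within 1.5 times of the main count, and for a main count of 0 again 0. For the TOX level it meant the same direction and side of the threshold. For a correlation it meant a change of less than 0.0735 between the lines or 0.0708 between the hairpins. With 1 array per line and construct, leaving out an array leaves some groups with a lone array, which is assumed to vary like the others; the number of arrays limits the precision. Quantile normalization, median centring, no filter and the mean over probe sets changed none of the counts beyond 1.5 times. Camera has no robust option, so lists under trend and robust were not run.

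The stricter filter, which tests fewer genes, gave 162 genes between scramble and untransduced arrays and r = 0.474 between the lines; trend gave 182 genes and trend with robust 220. Without the line term, which leaves the lines' differences in the error, 1 gene was called between shTOX and untransduced arrays and 0 between scramble and untransduced arrays, and TOX stood at -0.964 ± 0.363, past no threshold. Of the lists for shTOX against controls, 0 were called with an estimated correlation and 0 with fry. Without the untransduced arrays, chosen after seeing the data, TOX was at -0.952, past no threshold, and the lines correlated at -0.0522. Only scramble was then left as control, and that correlation is close to the -0.0515 found against scramble alone.

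With each array left out in turn, the genes called ranged from 0 to 4 for shTOX against controls, from 0 to 1 against scramble, from 29 to 1086 against untransduced and from 3 to 89 for scramble against untransduced. They ranged from 0 to 63 in CCRF-CEM, from 0 to 1 in HPB-ALL and from 0 to 4 for the difference between lines. TOX ranged from -1.21 to -0.644, lists called from 6 to 12, r between the lines from 0.0543 to 0.505 and r between hairpins from 0.131 to 0.246. For the hairpin contrast all counts were 0. The highest counts for shTOX against controls, in CCRF-CEM and for the difference between lines came without the CCRF-CEM scramble array. The untransduced array was then the only control of CCRF-CEM, so the shTOX difference there was that against untransduced cells. Other causes were not tested.

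The replicate block was a fit with the construct (shTOX-1, shTOX-2, scramble or untransduced) as a term shared by both lines. It called 16 genes for shTOX against controls, CCR8 (-2.16 ± 0.20) and MREG (0.79 ± 0.10) among them, 0 in each line, 0 for the difference between lines and 2907 between the lines. SOSTDC1 and KIF20A, called between scramble and untransduced arrays as well, were also among the 16. After removal of line and treatment means, arrays of the same construct correlated between lines at 0.225 for each hairpin and 0.371 for scramble and for untransduced; with 2 arrays per mean each pair of values is mirrored. Nothing in the labels pairs these arrays beyond the construct.

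Of 4268 recomputed values for 254 differences of named genes, 3891 kept their direction and side of the threshold, 352 no longer passed, 13 newly passed and 12, none of them passing, changed sign. TOX2 for shTOX against controls was 0.00144 with quantile normalization, and ranged from -0.104 to 0.132 with each array left out, above 0 without the scramble (0.0319), shTOX-2 (0.132) or untransduced array (0.000373) of HPB-ALL. Without the untransduced CCRF-CEM array TOX4 was 0.0752, RAG2 0.0569 and LAG3 0.00972, the highest of ranges whose lowest values were -0.101, -0.448 and -0.352; without both untransduced arrays they were 0.104, 0.155 and 0.0482. TOX between scramble and untransduced arrays ranged from -0.167 to 0.121, and was 0.0908 without the CCRF-CEM scramble array.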

Other observations

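In CCRF-CEM, more genes of thymocyte development set the untransduced array apart, chosen here after their values were seen. PTCRA, the partner chain of the pre-T cell receptor, was 11.15 untransduced, 7.84 with scramble, 9.07 with shTOX-1 and 8.64 with shTOX-2; NOTCH3 was 9.23, 6.63, 7.04 and 7.45, and the homing receptor CCR9 9.06, 6.64, 6.52 and 6.17. CD34, of early progenitors, was 5.52 untransduced, 8.05 with scramble, 8.48 with shTOX-1 and 8.55 with shTOX-2, and the interferon-induced GBP4 was 4.48, 7.26, 8.27 and 7.88. In HPB-ALL, THEMIS, a T cell receptor signalling protein of thymocytes, was 4.29 untransduced, 8.21 with scramble, 6.30 with shTOX-1 and 6.55 with shTOX-2. The lines are named here as in the labels, and their identity was not tested. Of the genes activated by rearrangement in some T-ALL, TLX3 was 5.48 to 5.74 and NKX2-5 8.84 to 10.15 over the 8 arrays.

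Of the splits of arrays tried against chance, those for lists and for the lines were planned before the results, and that for genes was written after them. For genes called between shTOX and controls, 34 of 34 splits of the arrays into 4 and 4 gave as many as the real 0 (highest other 1), which any split must, so this count decides nothing. For lists, 4 of 34 gave as many as the real 10 (highest other 13), so chance cannot be excluded. Most of the other splits also called some lists, so a camera call by itself is not particular to the shTOX grouping. For the lines only the real split, 1 of 34, gave its 2443 genes, with a highest other of 0. Every other split mixes the lines and leaves their difference in the error, so low counts there were close to fixed in advance. This test therefore cannot exclude chance.

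The untransduced arrays stood apart from the transduced arrays of both lines, and all tests of this were written after the result was seen, except that of 17 HPB-ALL genes for cells of the other line. Between 6 transduced and 2 untransduced arrays 984 genes were called, 533 higher in transduced, and this was the only one of 28 splits (1 of 28, highest other 0) to reach that count. Other splits leave that difference in the error, which lowers their counts. Of the 984 genes, 932 were still called after quantile normalization and 870 after median centring. The deposited values were already level across arrays, so a second scaling changes little and cannot test the authors' own normalization. Against cells of the other line as the whole cause, the difference correlated between the lines across all tested genes (r = 0.574). A mix would move the lines toward each other. Between arrays of different constructs r was at most 0.189. Each array was set against the others of its line, which ties these values together, so the 0.189 adds no support. Against cells without T cell receptor genes as the whole cause, these genes were higher untransduced. Their medians were 0.311 in CCRF-CEM and 0.446 in HPB-ALL (lower quartiles 0.0963 and 0.145), although 50 called genes were lower by at least 1. Relative to the HPB-ALL scramble array alone their median was 0.170, but their mean level was lower untransduced (7.455 against 7.527). The argument is therefore weaker in HPB-ALL. Other T cells mixed into both untransduced cultures were not tested and stay open. Open as a part are cells of the other line (17 HPB-ALL genes at a median of 0.0687 in the untransduced CCRF-CEM array, upper quartile 0.301; 71 CCRF-CEM genes at 0.0404 in that of HPB-ALL), blood cells of another type (highest marker median -0.0812, but 11 of 22 markers below the filter level, and CD68 and EPOR higher untransduced in both lines) and fibroblasts or epithelial cells (median 0.0312, upper quartile 0.275). The growth state of the cultures may contribute, as the difference was shared by the lines (r = 0.574), but it cannot be told apart from transduction and selection.

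The CD1 genes were lower in the shTOX arrays of CCRF-CEM, and all tests of this were chosen after the result was seen, on genes picked for it. Between the scramble and untransduced arrays, which have equal TOX, CD1A, CD1B, CD1C and CD1E differed by a median of -1.42 and CD1D by 0.656, and between the shTOX and scramble arrays the 5 genes differed by a median of -1.59 (-1.11 with shTOX-1 and -2.06 with shTOX-2). With 1 array per construct in this line, a lower TOX level, transduction and selection, and a chance difference between single cultures all stay open.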
